A study of Homo sapiens with 12 samples.

How the data were processed

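RNA was measured in A375 cells, a BRAF-mutant human melanoma line, treated for 24 h with DMSO (the solvent), with 1 µM XL413, with 1 µM GSK343, or with both compounds at 1 µM each. XL413 inhibits CDC7, the kinase that with its partner DBF4 starts DNA replication from licensed origins. GSK343 inhibits EZH2, the methyltransferase of a Polycomb repressive complex. Per the labels there were 3 biological replicates in each of the 4 groups, 12 libraries in all, made from poly-A RNA with a dUTP strand-specific protocol and sequenced on an Illumina HiSeq instrument.

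The deposited table holds RSEM expected counts, estimated read counts per gene that the authors made with Bowtie2 2.1.0 and RSEM 1.2.15 on hg38, not scaled between libraries. The values show this unit: 10.5 to 11.1% of the values of a library are not whole numbers, and the columns sum to 31553205 to 39079931. The gene annotation, the strand setting of the counting, read trimming and filters are not given in the sources used here. RSEM divides reads that match several genes by estimate, so the values of close paralogs, of overlapping antisense genes and of readthrough transcripts depend on that division. Each column is 1 library, and every column was assigned to its group and replicate number by the labels.

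The table has 26475 genes with 26473 distinct names. Of these, 28 names look like calendar dates, as a spreadsheet makes them from symbols, and 2 of them occur on 4 lines; these genes were kept in the fits under their date-like names, and none is discussed by name. Gene positions, GC content and transcript lengths came from GENCODE 29 on GRCh38, with GC content and length those of each gene's longest transcript in the basic set. By name, 23872 genes matched directly and 752 through an older symbol, and 1849 did not match.

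Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups (minimum count 10, minimum total 15), which left 15443 tested genes and removed 11032. Libraries were scaled by TMM, and 1 quasi-likelihood model with a coefficient per group was fitted to all 12 libraries, with 8 residual degrees of freedom. Contrasts were XL413, GSK343 and the combination each against DMSO, the combination against each single compound, and the interaction, which is the GSK343 effect with XL413 minus the GSK343 effect without it. Tests were two-sided with Benjamini-Hochberg adjustment over the tested genes, and a gene was called at an adjusted p under 0.05. Each standard error (SE) is the size of the log2 fold change divided by the root of the F statistic. Levels are CPM, counts scaled to the effective library size, as mean ± SD of 3 libraries.

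Before the data were examined, the groups, the contrasts, these settings, 28 gene lists, the rule for naming genes and the alternatives were fixed, except where a choice is said to come later. The lists were compound targets and partners, MCM helicase and origin licensing, G1/S and E2F targets, G2/M and mitosis, replication-dependent histones, p53 targets, DNA repair by homologous recombination and Fanconi genes, the BCL-2 family, cholesterol synthesis and uptake, fatty acid synthesis, lysosome and autophagy, ATF4 targets, endoplasmic reticulum chaperones, interferon-stimulated genes, antigen presentation, NF-kB and secreted inflammatory factors, MAPK output, melanocyte differentiation, the undifferentiated melanoma state, HOX genes, other Polycomb-target developmental regulators, NRF2 targets, hypoxia and glycolysis, heat shock, mitochondrially encoded mRNAs, and markers of epithelial cells, fibroblasts and leukocytes. Some genes stand in 2 lists. The 13 mitochondrially encoded mRNAs were not analysed, since 0 of them are in the table. The other 27 lists had at least 5 tested members and were tested against the remaining genes with camera of limma 3.58.1, with its preset inter-gene correlation of 0.01 and adjustment over the lists. Each list's members were also counted with p adjusted over the list alone, and each list was tested again with an estimated correlation and with fry.

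Named genes are, for each comparison, the 6 with the largest rise and the 6 with the largest fall among called genes that had a mean of at least 1 log2 CPM, a proper symbol, and all 3 libraries of one group beyond all 3 of the other. To these were added the compound targets and partners, up to 4 members with the smallest p of each list past its test, and up to 2 members with the highest level of each other list. Any other gene is said to be chosen after its values were seen.

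The alternatives were size factors of the DESeq2 kind (RLE), upper quartile scaling, no filter, a stricter filter (at least 5 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a minimum of 2-fold, the replicate number as a term of the model, and leaving out each library in turn. After the data were seen, a correction for GC content and transcript length was added, with trends fitted for each library by mgcv 1.9.3 over the 14979 tested genes (97%) that have both values, as were 2 contrasts that average each compound's effect without and with the other. Figures were drawn with matplotlib 3.10.9.

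The procedure was tested on simulated data in which known genes were changed in the counts of each of the 3 treated groups. At 1.5-fold it called 92.5% of the changed genes in the XL413 comparison, 95.5% in the GSK343 comparison and 92.5% in the combination comparison, and at 1.25-fold 47.8%, 47.8% and 50.7%. False calls made up 5.2%, 4.09% and 5.75% of all calls. In these simulations genes changed by 1.25-fold were therefore often missed. At each fold 66 or 67 genes were changed, drawn from those above a minimum level, at the spread of all 12 libraries. The rates need not hold where more genes change or the spread differs. With the combination the 2152 called genes had a median fold of 1.2. Precision followed from the replicates and from depths of 31553205 to 39079931 counts, and repeated reads of 1 molecule cannot be told from separate molecules in these counts.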

Results

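Poly-A RNA of A375 melanoma cells was sequenced after 24 h with DMSO, the CDC7 inhibitor XL413, the EZH2 inhibitor GSK343, or both compounds, with 3 libraries in each of 4 groups. Total expected counts, in the order of the replicate numbers, were 33410559, 33844765 and 33355678 in the DMSO libraries and 34293026, 31553205 and 35777606 with XL413. They were 32979558, 34389768 and 36131973 with GSK343, and 32153099, 39079931 and 34732148 with the combination. A count was present for 18239 to 18551 genes per library, and 15443 genes were tested.

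GSK343+XL413 replicate 2 stood apart from the other libraries. The SD across 12177 genes of its deviation from the other 2 libraries of its group, on the log2 scale, was 0.276, against 0.132 to 0.176 for the other 11 libraries. Its deviation fell with transcript length (Spearman's rho across genes −0.641, against −0.448 to 0.565 in the other libraries; genes are not independent replicates). The first principal component held 33.7% of the variance, and this library lay at 28.5 on it, with the other libraries between −9.9 and 3.6. All comparisons shared 1 estimate of the spread, and the median SE of XL413 against DMSO, which does not involve this library, was 0.063 with it and 0.0481 without it.

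**Figure D1:**
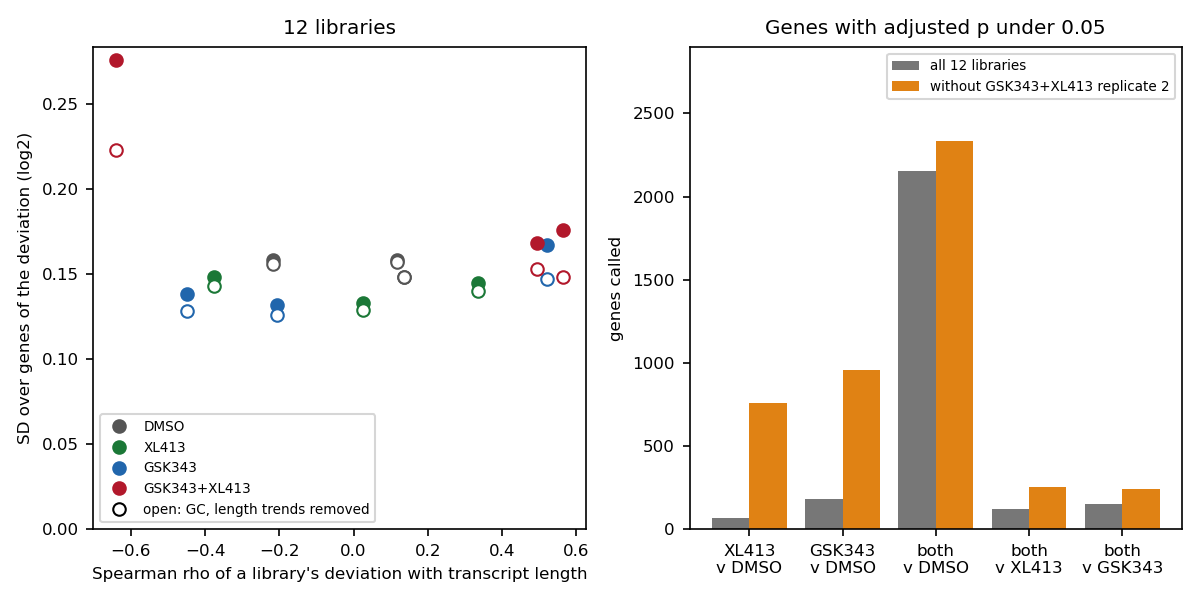
Left, for each of the 12 libraries, Spearman's rho across genes between transcript length and the library's deviation from the other 2 of its group (horizontal) and the SD of that deviation on the log2 scale (vertical), with filled points for the counts as scaled and open points after GC and length trends were removed. Right, the number of genes called in each comparison with all 12 libraries and without GSK343+XL413 replicate 2; without that library, which lies at −0.641 and 0.276 on the left, the calls for XL413 against DMSO go from 66 to 756 and those for GSK343 against DMSO from 180 to 958.

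XL413 against DMSO asked what this compound alone changed, with 3 libraries on each side. The counts hold no direct measure of CDC7 activity, so the changes are those of the compound, whether or not through CDC7. The lists of mitosis, of histones and of secreted inflammatory factors were higher by camera, with 6 of 32, 3 of 13 and 6 of 23 members called. HMMR, which encodes a spindle-associated hyaluronan receptor (chromosome 5, 163460203 to 163491945 of hg38), rose from 74.9 ± 1.18 to 111 ± 2.60 CPM, a log2 fold change of 0.56 ± 0.045 (SE, adjusted p = 0.000189). CDK1, the kinase that drives entry into mitosis (chromosome 10, 60778331 to 60794852), rose by 0.43 ± 0.046, from 105 ± 0.951 to 142 ± 5.54 CPM. HIST1H2AC, a histone H2A gene (chromosome 6, 26124145 to 26139116), rose by 0.88 ± 0.098, from 5.12 ± 0.508 to 9.44 ± 0.260 CPM. AXL, a receptor tyrosine kinase of the undifferentiated melanoma state (chromosome 19, 41219203 to 41261766), fell by 0.38 ± 0.049, from 478 ± 7.94 to 367 ± 17.9 CPM.

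Of 32 tested genes of G2/M and mitosis, 6 rose and 26 were not called after XL413, and 16 rose when adjusted over the list alone (camera adjusted p = 4.47e-13, median log2 fold change 0.0943). MKI67 and CENPE, chosen here after their values were seen, were lower in all 3 XL413 libraries than in any DMSO library. MKI67 was at 425.2, 395.4 and 401.5 CPM, against 530.5, 556 and 555.3, but 0 genes of the list were called lower by either adjustment. UBE2C, an E2 enzyme of the anaphase-promoting complex, rose by 0.46 ± 0.064 and AURKA, the centrosomal kinase Aurora A, by 0.22 ± 0.030, and both calls were lost without DMSO replicate 2 (adjusted p = 0.0538 and 0.0549). Among 20 genes of the MCM helicase and of origin licensing, whose helicase subunits are the substrates of CDC7, MCM3 rose by 0.28 ± 0.038 and 19 were not called, with 2 rises adjusted over the list alone (median 0.066, adjusted p = 0.00615, and 0.0507 with an estimated correlation). Histones gave 3 rises among 13 tested genes and 4 adjusted over the list alone (median 0.219, adjusted p = 8.26e-10). HIST1H2BK rose by 0.69 ± 0.096, and HIST1H2BD by 0.78 ± 0.126, a call lost without DMSO replicate 2 or 3 or any XL413 library (adjusted p up to 0.0894). Histone genes of this class are close paralogs and most of their mRNA lacks a poly-A tail, so that these values cover only the polyadenylated part.

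Of 23 NF-kB and secreted inflammatory genes, 6 rose and 17 were not called after XL413, and 13 rose and 1 fell when adjusted over the list alone (median 0.225, adjusted p = 4.1e-16). The chemokine genes CCL2, CXCL8 and CXCL1 rose by 0.67 ± 0.087, 0.39 ± 0.053 and 0.38 ± 0.049. ICAM1, which encodes an adhesion molecule for leukocytes, rose by 0.33 ± 0.048, a call lost without DMSO replicate 2 or 3 or XL413 replicate 2 (adjusted p up to 0.0628). ATF4 targets, among them genes of amino acid synthesis and transport, were lower as a list (median −0.102, adjusted p = 8.54e-06, and 0.0895 with an estimated correlation). The 20 members were each not called over all genes, with 1 rise and 9 falls adjusted over the list alone. SLC7A5, which encodes an amino acid transporter, was at −0.27 ± 0.056 (adjusted p = 0.0615).

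Lysosome and autophagy genes gave 0 calls of 26 with XL413 and 3 rises adjusted over the list alone (median 0.0292, adjusted p = 0.012, and 0.327 with an estimated correlation). Antigen presentation gave 0 of 20 by either adjustment (median 0.0906, adjusted p = 0.012, and 0.402 with an estimated correlation). The antigen presentation call was lost without DMSO replicate 3 (adjusted p = 0.0724). For heat shock genes, 1 of 15 fell and 2 fell adjusted over the list alone (median −0.0472, adjusted p = 0.032, and 0.117 with an estimated correlation). HSPA1A, which encodes the inducible chaperone HSP70, fell by 0.23 ± 0.045, but that call held only without XL413 replicate 3 or GSK343+XL413 replicate 2 (adjusted p up to 0.257 in the other fits that left out 1 library). The heat shock list itself was lost without DMSO replicate 1 or 3, GSK343 replicate 2 or 3, XL413 replicate 1 or GSK343+XL413 replicate 1 (adjusted p up to 0.175). Leukocyte markers, of which 6 of 13 were tested, gave 0 calls over all genes and 3 rises and 1 fall adjusted over the list alone. Their median was 0.264 (adjusted p = 0.0154, and 0.173 with an estimated correlation), and the call was lost without DMSO replicate 3 or XL413 replicate 2 (adjusted p up to 0.0595). LAPTM5, a lysosomal protein gene of that list, was at 1.73 ± 0.411 CPM with DMSO and 3.01 ± 0.451 with XL413 (adjusted p = 0.0858).

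With edgeR, 66 genes were called after XL413, 43 higher and 23 lower, with a median fold of 1.25, and 2114 genes had an unadjusted p under 0.05. Upper quartile scaling gave 43 higher and 14 lower, and DESeq2 124 and 121. The balance turned to lower with the GC and length correction, added after the data were seen (236 and 340), and without GSK343+XL413 replicate 2 (353 and 403). Log2 fold changes fell with transcript length (rho −0.252 across genes). Median lengths were 2452.5 nt for higher and 2909 nt for lower called genes, and the cause was not tested. At least 2-fold, 1 gene was called, TRIM34 (2.13-fold, log2 1.09 ± 0.21, at a mean of 0.92 log2 CPM), chosen after its value was seen. That call was kept in 3 of 12 fits that left out 1 library (adjusted p up to 0.21). Among the genes with the largest changes, LRRC17 rose by 0.70 ± 0.105 (lost without DMSO replicate 2 or XL413 replicate 2 or 3, adjusted p up to 0.0687), and CALB2, ADAMTS6, BCYRN1, ST8SIA4 and S1PR1 fell by 0.37, 0.56, 0.58, 0.48 and 0.38. CALB2 was lost without DMSO replicate 1 or 2 or XL413 replicate 1 or 3 (adjusted p up to 0.0664), ADAMTS6 without DMSO replicate 1 or 3 or any XL413 library (0.16), and BCYRN1 without any DMSO or XL413 library (0.117). ST8SIA4 was kept only without GSK343+XL413 replicate 1 or 2, and S1PR1 only without DMSO replicate 1, GSK343 replicate 3 or GSK343+XL413 replicate 2 (up to 0.223 and 0.204). The 66 calls became 29, 16 and 23 without DMSO replicates 1, 2 and 3, 25, 18 and 22 without XL413 replicates 1, 2 and 3, and 756 without GSK343+XL413 replicate 2, which kept all 66. DESeq2 called 245 genes, a fit of the 6 libraries alone 1333 (660 higher and 673 lower), and the GC and length correction 576.

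GSK343 against DMSO asked what this compound alone changed, again with 3 libraries on each side. The counts hold no direct measure of EZH2 activity, so the changes are those of the compound, whether or not through EZH2. Genes of cholesterol synthesis were higher as a list by camera, with 14 of 24 called. HMGCS1, an early enzyme of cholesterol synthesis (chromosome 5, 43289395 to 43313512), rose from 41.7 ± 1.40 to 66.7 ± 1.70 CPM, a log2 fold change of 0.68 ± 0.044 (adjusted p = 1.4e-05). INSIG1, an endoplasmic reticulum protein that holds back the sterol-sensing transcription factors (chromosome 7, 155297776 to 155310235), rose by 0.71 ± 0.068. MMP3, a secreted metalloproteinase (chromosome 11, 102835801 to 102843803), rose by 0.87 ± 0.089, from 8.198 ± 1.10 to 15 ± 1.07 CPM, and PTGES, the prostaglandin E synthase (chromosome 9, 129738331 to 129753047), by 0.88 ± 0.077. HSPA1A (chromosome 6, 31815464 to 31817946) fell by 0.45 ± 0.045, from 143 ± 3.04 to 105 ± 1.11 CPM, and PSAT1, an enzyme of serine synthesis (chromosome 9, 78297143 to 78330093), by 0.33 ± 0.035, from 392 ± 3.37 to 311.8 ± 3.004 CPM.

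Of 24 tested genes of cholesterol synthesis and uptake, 14 rose and 10 were not called with GSK343, and 18 rose when adjusted over the list alone (median 0.314, 1.24-fold, camera adjusted p = 1.17e-45). DHCR7, the enzyme of the last step of cholesterol synthesis, rose by 0.41 ± 0.046 and FDFT1, the squalene synthase, by 0.37 ± 0.044. SREBF1, a transcription factor of fatty acid synthesis, fell by 0.33 ± 0.048 (lost without DMSO replicate 2, adjusted p = 0.0522). In the fatty acid synthesis list, 2 of 13 rose, 1 fell and 10 were not called, with 3 rises and 1 fall adjusted over the list alone (median 0.0659, adjusted p = 0.0368, and 0.297 with an estimated correlation). That list call was lost without DMSO replicate 1, GSK343 replicate 2 or 3 or XL413 replicate 3 (adjusted p up to 0.111).

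NF-kB and secreted inflammatory genes gave 6 rises and 17 genes not called of 23 with GSK343, and 12 rises adjusted over the list alone (median 0.218, adjusted p = 2.92e-13). Besides MMP3, the cytokine gene IL24 rose by 0.63 ± 0.066. Of 15 heat shock genes, 6 fell and 9 were not called, and 10 fell adjusted over the list alone (median −0.131, adjusted p = 2.92e-13). HSPA1B, a paralog nearly identical to HSPA1A, fell by 0.46 ± 0.061, and the division of reads between the 2 genes is an estimate. ATF4 targets gave 5 falls and 15 genes not called of 20, and 1 rise and 11 falls adjusted over the list alone (median −0.154, adjusted p = 6.75e-11). Falls of PHGDH, ASNS and MTHFD2, of serine, asparagine and one-carbon metabolism, were 0.25 ± 0.039, 0.25 ± 0.041 and 0.20 ± 0.034, and TRIB3, chosen after its value was seen, fell by 0.26 ± 0.052. The first 3 calls were lost without any DMSO library, and also without GSK343 replicate 3 for PHGDH, 2 or 3 for ASNS and 2 for MTHFD2 (adjusted p up to 0.0688, 0.073 and 0.0777).

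Lists of the cell cycle were lower with GSK343. Of 20 MCM and licensing genes, 2 fell and 18 were not called, and 10 fell adjusted over the list alone (median −0.108, adjusted p = 1.06e-08). Of 28 G1/S and E2F targets, 3 fell and 25 were not called, and 9 fell adjusted over the list alone (median −0.116, adjusted p = 5.75e-10). G2/M and mitosis gave 3 falls and 29 genes not called of 32, and 6 falls adjusted over the list alone (median −0.0776, adjusted p = 1.75e-06). Among them were the helicase genes MCM7 and MCM4 (−0.15 ± 0.030 and −0.14 ± 0.030), UHRF1, a factor of maintenance methylation (−0.22 ± 0.044), the mitotic kinase gene PLK1 (−0.19 ± 0.033) and CDC20, an activator of the anaphase-promoting complex (−0.21 ± 0.038). These 5 calls were each lost without any 1 of the DMSO or GSK343 libraries (adjusted p up to 0.165, 0.224, 0.16, 0.102 and 0.116). MCM7 was kept only without GSK343+XL413 replicate 2 or 3, MCM4 only without replicate 2, and UHRF1 only without XL413 replicate 3 or any GSK343+XL413 library. The 3 list calls held in all 12 fits that left out 1 library and with an estimated correlation.

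SQSTM1, the autophagy receptor p62, rose by 0.43 ± 0.049 with GSK343, from 595 ± 6.13 to 801 ± 49.9 CPM, and GPNMB, a melanosomal glycoprotein gene, by 0.51 ± 0.044, from 47.1 ± 1.26 to 67.3 ± 0.718 CPM. In the lysosome and autophagy list, SQSTM1 and WIPI1 rose and 24 of 26 were not called, with 3 rises adjusted over the list alone (median 0.0406, adjusted p = 0.0108, and 0.223 with an estimated correlation), a call lost without GSK343 replicate 1 (adjusted p = 0.0644). WIPI1, a gene of autophagosome formation, rose by 0.41 ± 0.083, a call lost without DMSO replicate 1 or 3, any GSK343 library or XL413 replicate 3 (adjusted p up to 0.158). GPNMB was the 1 called gene of 14 in the melanocyte list by either adjustment (median 0.111, adjusted p = 0.0348, and 0.113 with an estimated correlation), lost without DMSO replicate 2 or GSK343 replicate 2 (adjusted p up to 0.0939). Of 33 interferon-stimulated genes, OAS1, a sensor of double-stranded RNA, rose by 0.62 ± 0.126 and 32 were not called, 3 rose adjusted over the list alone, and 32 had an estimate above 0 (median 0.284, adjusted p = 6.49e-10, and 0.185 with an estimated correlation). The OAS1 call was lost without DMSO replicate 2 or 3, any GSK343 library or XL413 replicate 2 (adjusted p up to 0.165). Antigen presentation gave 0 calls of 20 over all genes and 3 rises adjusted over the list alone (median 0.11, adjusted p = 0.000464, and 0.185 with an estimated correlation).

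Hypoxia and glycolysis genes gave 3 rises, 1 fall and 17 genes not called of 21 with GSK343, and 7 rises and 2 falls adjusted over the list alone (median 0.0622, adjusted p = 0.00328). CA9, a carbonic anhydrase induced by hypoxia, rose by 1.10 ± 0.189 from 1.52 ± 0.458 to 3.27 ± 0.250 CPM, PFKFB4 by 0.29 ± 0.049 and the aldolase gene ALDOC by 0.38 ± 0.068, and the glucose transporter gene SLC2A1 fell by 0.17 ± 0.032. CA9 was lost without DMSO or GSK343 replicate 1 or 3, PFKFB4 without any DMSO library or GSK343 replicate 2 or 3 (adjusted p up to 0.083 and 0.0772). ALDOC was lost without any DMSO library or GSK343 replicate 1 or 3, and SLC2A1 without any DMSO or GSK343 library or XL413 replicate 1 or 2 (up to 0.0963 and 0.155). Other lists past the test had no called member: histones (median 0.204, adjusted p = 0.0348, and 0.214 with an estimated correlation), homologous recombination and Fanconi genes (median −0.0816, adjusted p = 0.00602, and 0.206) and epithelial markers (median −0.158, adjusted p = 0.0299, and 0.223). Adjusted over the list alone they had 0, 0 and 2 called genes, the last 2 lower. The call for histones was lost without DMSO replicate 2, GSK343 replicate 1 or 2 or GSK343+XL413 replicate 2 (adjusted p up to 0.0859), and that for repair genes without GSK343 replicate 2 (0.0663). The call for epithelial markers was kept only without DMSO replicate 3, GSK343 replicate 2 or GSK343+XL413 replicate 1 or 3 (up to 0.14).

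EZH2 acts on developmental regulators, of which 36 of 39 HOX genes and 47 of 60 other Polycomb targets were tested. The count filter removed the rest, so that a rise of these too small to pass it would not be seen. By either adjustment 0 HOX genes were called with GSK343 (median 0.0048, mean −0.012, adjusted p = 0.855). CDKN1C, a cell cycle inhibitor gene chosen after its value was seen, was the 1 called gene of the other list, at 0.44 ± 0.086 (median −0.010, mean 0.012, adjusted p = 0.896). EZH2 mRNA was at 96.8 ± 3.58 CPM with DMSO and 88.4 ± 1.97 with GSK343 (log2 −0.13 ± 0.041, adjusted p = 0.162), and SUZ12, EED and EZH1 were at −0.06 ± 0.054, −0.08 ± 0.058 and 0.05 ± 0.054. CDC7 mRNA was at −0.01 ± 0.056 with XL413 (adjusted p = 0.952), and its partners DBF4 and DBF4B at 0.09 ± 0.044 and −0.10 ± 0.076.

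With edgeR, 180 genes were called after GSK343, 112 higher and 68 lower, with a median fold of 1.23, and 2201 had an unadjusted p under 0.05. Upper quartile scaling gave 136 higher and 31 lower, and DESeq2 169 of each. The balance turned to lower with the GC and length correction (269 and 382) and without GSK343+XL413 replicate 2 (399 and 559). Log2 fold changes fell with GC content (rho −0.265 across genes). Median GC content was 46.5% for higher and 57.6% for lower called genes, and the cause was not tested. At least 2-fold, 4 genes were called, all higher: CA9, and, chosen after their values were seen, TRIM34 (2.69-fold), C15orf48 (2.07-fold) and KRT75 (3.57-fold, at a mean of −1.34 log2 CPM). The largest changes also took in PCSK1, ID2 and PADI3, which rose by 0.98 ± 0.166, 0.77 ± 0.126 and 0.76 ± 0.140, and CBS and PLEKHH3, which fell by 0.34 ± 0.060 and 0.33 ± 0.062. Their adjusted p went up to 0.0774, 0.0592, 0.114, 0.0963 and 0.126 when 1 library was left out. PCSK1 was lost without DMSO replicate 2 or 3 or GSK343 replicate 1 or 2, ID2 without DMSO replicate 1 or 3 or GSK343 replicate 3, PADI3 without any of these 6 libraries, and CBS and PLEKHH3 without any DMSO library or GSK343 replicate 1 or 3. The 180 calls became 47, 38 and 37 without DMSO replicates 1, 2 and 3, 68, 68 and 62 without GSK343 replicates 1, 2 and 3, 119 without XL413 replicate 2, and 958 without GSK343+XL413 replicate 2, which kept all 180. A fit of the 6 libraries alone called 408 genes (216 higher and 192 lower) and the GC and length correction 651.

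**Figure D2:**
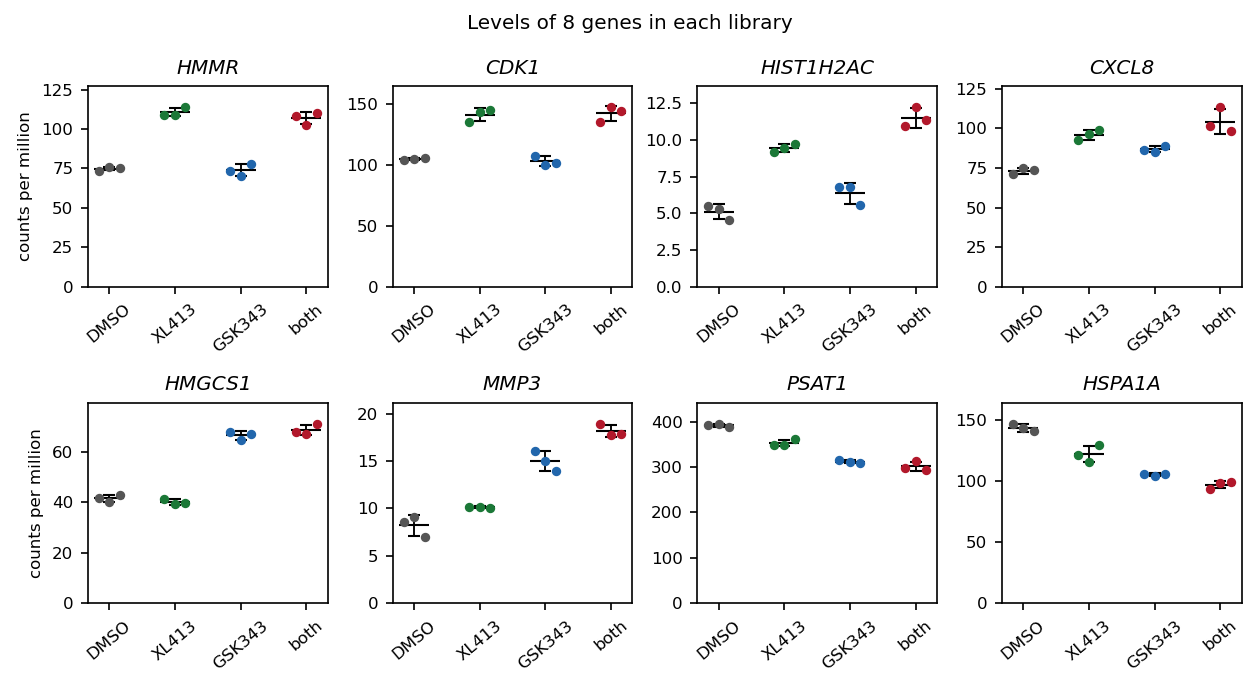
Level in CPM (vertical axes from 0) of 8 genes in the 12 libraries by group, with points for libraries and bars for the mean ± SD of 3. HMMR and CDK1 were higher in both groups with XL413, and HMGCS1 in both groups with GSK343 (66.7 and 68.8 CPM, against 41.7 and 40.2 without it).

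GSK343+XL413 against DMSO asked what both compounds changed together, with 3 libraries on each side. Histone, cholesterol and secreted inflammatory lists, each higher with a single compound, were also higher here by camera. The mitotic and the MCM and licensing lists, higher with XL413 (the latter with an adjusted p of 0.0507 at an estimated correlation) and lower with GSK343, did not pass here, and neither did the hypoxia list, higher with GSK343. HIST1H2AC rose by 1.17 ± 0.097, to 11.5 ± 0.651 CPM (adjusted p = 3.76e-05), MMP3 by 1.15 ± 0.088, to 18.2 ± 0.637 CPM, and HMGCS1 by 0.72 ± 0.044, to 68.8 ± 2.13 CPM. MMP1, a collagenase gene, rose by 0.86 ± 0.066, and CCL2 by 0.91 ± 0.086. HSPA1A fell by 0.56 ± 0.045 and PSAT1 by 0.38 ± 0.035. CENPE, a kinesin that carries chromosomes to the spindle equator (chromosome 4, 103105806 to 103198409), fell by 0.80 ± 0.113, from 64.1 ± 2.15 to 37.0 ± 7.42 CPM.

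Cholesterol genes gave 17 rises and 7 genes not called of 24 with the combination, and 22 rises adjusted over the list alone (median 0.328, camera adjusted p = 8.4e-29). MSMO1, FDFT1 and INSIG1 rose by 0.64 ± 0.066, 0.53 ± 0.044 and 0.65 ± 0.068. Of the NF-kB and secreted inflammatory genes, 13 of 23 rose and 10 were not called, and 15 rose adjusted over the list alone (median 0.291, adjusted p = 1.37e-17), with CXCL8 at 0.51 ± 0.053. Among 20 ATF4 targets 13 fell, 2 rose and 5 were not called, and 14 fell and 2 rose adjusted over the list alone (median −0.199, adjusted p = 2.4e-08). ASNS, SLC7A5 and SHMT2 fell by 0.34 ± 0.041, 0.45 ± 0.056 and 0.23 ± 0.036, whereas STC2 and CEBPB, chosen after their values were seen, rose by 0.25 ± 0.055 and 0.34 ± 0.080. In the heat shock list 8 of 15 fell and 7 were not called, and 9 fell adjusted over the list alone (median −0.103, adjusted p = 6.35e-07), with HSPA1B, DNAJB1 and STIP1 at −0.63 ± 0.061, −0.25 ± 0.035 and −0.17 ± 0.030.

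Histones gave 5 rises and 8 genes not called of 13 with the combination, and 6 rises adjusted over the list alone (median 0.38, adjusted p = 1.98e-07). HIST1H2BK and HIST1H2BD rose by 0.90 ± 0.095 and 1.00 ± 0.124, HIST1H1C by 0.38 ± 0.087 (lost without DMSO replicate 3, adjusted p = 0.0636), and HIST1H2BJ, chosen after its value was seen, by 0.89 ± 0.267. In the lysosome and autophagy list 10 of 26 rose and 16 were not called, with 11 rises and 1 fall adjusted over the list alone (median 0.0985, adjusted p = 2.64e-05, and 0.113 with an estimated correlation). SQSTM1 rose by 0.50 ± 0.049, WIPI1 by 0.47 ± 0.083, and NPC2 and PSAP, genes of lysosomal lipid handling, by 0.32 ± 0.060 and 0.19 ± 0.037. Antigen presentation gave 8 rises and 12 genes not called of 20, with 12 rises and 1 fall adjusted over the list alone (median 0.177, adjusted p = 3.75e-05, and 0.149 with an estimated correlation). The class II genes HLA-DRA, HLA-DPA1 and HLA-DMA rose by 0.36 ± 0.051, 0.29 ± 0.043 and 0.35 ± 0.065, and B2M, the light chain of class I, by 0.35 ± 0.066.

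Interferon-stimulated genes gave 5 rises and 28 genes not called of 33 with the combination by either adjustment (median 0.221, adjusted p = 0.00255, and 0.461 with an estimated correlation), a call lost without DMSO replicate 3 or GSK343+XL413 replicate 3 (adjusted p up to 0.0945). ISG20, UBE2L6, OAS1 and IFI44 rose by 0.35 ± 0.057, 0.29 ± 0.049, 0.50 ± 0.126 and 0.26 ± 0.065, and CXCL10, chosen after its value was seen, by 1.14 ± 0.330. OAS1 was lost without DMSO replicate 2 or 3 (adjusted p up to 0.0935) and IFI44 without DMSO replicate 3 (0.0963). Of the leukocyte markers, LAPTM5 and LYZ rose by 0.91 ± 0.183 and 0.39 ± 0.086, to 3.27 ± 0.448 and 6.98 ± 0.502 CPM. The other 4 of 6 were not called, with 4 rises adjusted over the list alone (median 0.252, adjusted p = 0.0294, and 0.192 with an estimated correlation). The leukocyte call was lost without DMSO replicate 3 or GSK343+XL413 replicate 2 (adjusted p up to 0.103).

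Mitotic genes went both ways with the combination: of 32, 10 rose, 6 fell and 16 were not called, and 11 rose and 9 fell adjusted over the list alone (median 0.038, mean −0.0059, adjusted p = 0.212). HMMR, CDK1 and UBE2C, chosen here after their values were seen, rose by 0.52 ± 0.045, 0.44 ± 0.046 and 0.51 ± 0.064. Besides CENPE, MKI67, which encodes the proliferation antigen Ki-67 (chromosome 10, 128096659 to 128126385), fell by 0.76 ± 0.173, with 379 and 392 CPM in GSK343+XL413 replicates 1 and 3, 201 CPM in replicate 2, and 547 ± 14.5 CPM with DMSO. ASPM, CENPF, KIF11 and PLK1, chosen after their values were seen, fell by 0.49 ± 0.123, 0.58 ± 0.137, 0.25 ± 0.057 and 0.19 ± 0.033. Transcripts of the 6 lower genes had a median length of 9459.5 nt and those of the 10 higher genes 2150 nt, the direction in which GSK343+XL413 replicate 2 deviated from its group. A length trend in the same direction was present for XL413 against DMSO (rho −0.252 across genes), a comparison that does not involve that library. Without that library the median log2 fold change of the 6 went from −0.537 to −0.342, and all 6 stayed called.

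Lists that did not pass the test in this comparison had called members in both directions or few of them; those named next were chosen after their values were seen, except EZH2, DBF4B, RRM2, PLK2, FASN, CCND1, EPHA2, FTH1 and FTL. MCM and licensing genes (adjusted p = 0.338) included MCM3, which rose, and CDC6, which fell, and 4 of 28 G1/S genes fell (0.0748), UHRF1, RRM2, CHAF1A and CCNE2. Of 25 p53 targets (0.609), GDF15, CCNG1, TP53I3 and SESN1 rose and PLK2 fell. CHEK2 rose and FANCA and RAD54L fell among repair genes (0.0757), ACSS2 and ME1 rose and SREBF1 and FASN fell among 13 fatty acid genes (0.613). BCL2L1 fell by 0.22 ± 0.037 among 15 genes of the BCL-2 family (median 0.014, mean 0.041, with camera's direction down, 0.955). CRELD2 rose among 17 endoplasmic reticulum chaperones (0.955). Of 21 genes of MAPK output (0.212), LIF, IER3 and DUSP6 rose and EPHA2, CCND1, FOSL1 and ETV4 fell, and of 23 genes of the undifferentiated state (0.212), TGFBI, ANKRD1 and TWIST1 rose and AXL, AMOTL2, CD44 and CDH2 fell. GPNMB rose among melanocyte genes (0.338), HOXA6 fell among HOX genes (median 0.015, mean −0.023, 0.955), and KLF4 rose and SOX9 and EN1 fell among the other Polycomb targets (0.639). Of 17 NRF2 targets (0.212), ME1 and the ferritin genes FTH1 and FTL rose and SLC7A11 fell. PFKFB4, ANGPTL4 and ALDOC rose and SLC2A1 and HK2 fell in the hypoxia list (0.955), LUM rose among fibroblast markers (0.533), and 0 of 11 epithelial markers were called (0.955). Of the compound targets and partners (0.338), EZH2 fell by 0.15 ± 0.041 (lost without any DMSO library or GSK343+XL413 replicate 3, adjusted p up to 0.127) and DBF4B by 0.28 ± 0.076 (lost without any DMSO library or GSK343+XL413 replicate 2, adjusted p up to 0.0908).

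With edgeR, 2152 genes were called with the combination, 1033 higher and 1119 lower, with a median fold of 1.2, and 4687 had an unadjusted p under 0.05. Upper quartile scaling gave 1367 higher and 778 lower. Of the 2152 genes, 196 were also called with a single compound and 1956 (90.9%) with neither. The share with neither was 54% (1261 of 2335 genes) without GSK343+XL413 replicate 2, 91.9 to 95.1% without any other library, and 70.1% with the GC and length correction. The 196 became 1074 without GSK343+XL413 replicate 2, 67, 47 and 52 without DMSO replicates 1, 2 and 3, 103 and 106 without GSK343 replicates 1 and 3 (without its replicate 2, all but 1675 of 1776), and 121 and 114 without XL413 replicates 1 and 2; the 1956 became 1060, 803 and 1003 without the DMSO replicates and 1261 without GSK343+XL413 replicate 2. Higher genes had a median transcript length of 2252 nt and lower genes of 4260 nt (rho of the log2 fold change with length −0.396 across genes). At least 2-fold, 41 genes were higher and 7 lower. C4orf48, PCSK1 and TENM1 had large rises (1.19 ± 0.324, 1.16 ± 0.164 and 0.93 ± 0.206), the first lost without DMSO replicate 1 or 2 or GSK343+XL413 replicate 1 or 2 (adjusted p up to 0.125) and the third without DMSO replicate 1 (0.0521). SENP3-EIF4A1, ADM2, AKAP9 and MUC5B had large falls (1.40 ± 0.274 for the first, a readthrough transcript whose reads overlap SENP3 and EIF4A1, then 1.00 ± 0.213, 0.77 ± 0.136 and 0.77 ± 0.164). In GSK343+XL413 replicates 1, 2 and 3 AKAP9 was at 38.78, 24.95 and 41.2 CPM and MUC5B at 16.37, 9.675 and 17.59 CPM. The size of both falls thus rests in part on replicate 2, though both calls were kept in all 12 fits that left out 1 library. The 2152 calls became 1127, 850 and 1055 without DMSO replicates 1, 2 and 3, and a fit of the 6 libraries alone called 671.

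**Figure D3:**
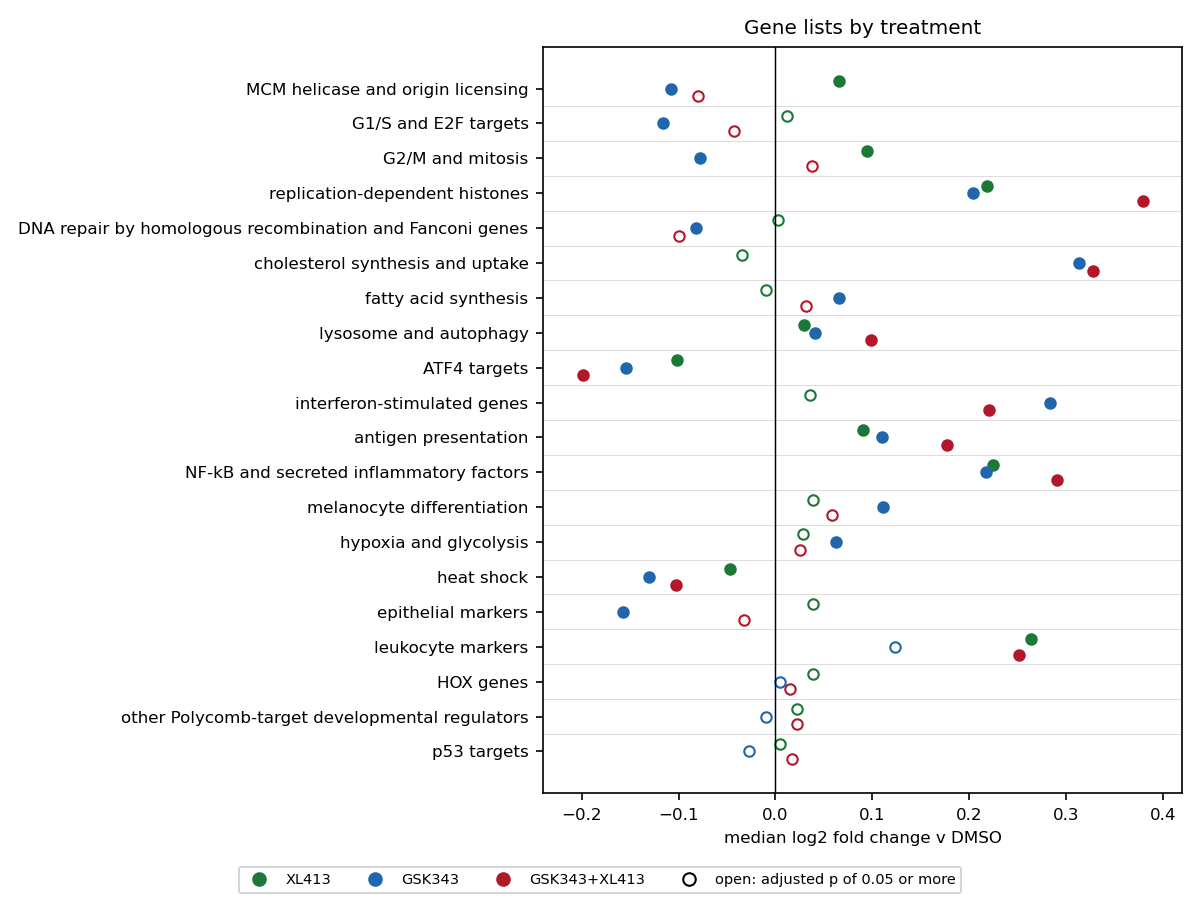
Median log2 fold change against DMSO (horizontal) of 20 gene lists (vertical) with XL413 (green), GSK343 (blue) and both (red), 1 point per list and comparison, open where the adjusted p of camera was 0.05 or more. Cholesterol synthesis was at 0.314 and 0.328 with GSK343 and both, and G2/M and mitosis at 0.0943 with XL413, −0.0776 with GSK343 and 0.038 with both.

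GSK343+XL413 against XL413 asked what GSK343 changed when XL413 was present. HMGCS1 rose by 0.78 ± 0.044 (adjusted p = 2.51e-06), from 40.2 ± 1.199 to 68.8 ± 2.13 CPM, and INSIG1 by 0.74 ± 0.068. STARD4, a cholesterol carrier, rose by 0.76 ± 0.093, SQLE, the squalene epoxidase, by 0.50 ± 0.043, MMP3 by 0.84 ± 0.086 and PTGES by 0.71 ± 0.076. HSPA1A fell by 0.33 ± 0.045, PSAT1 by 0.23 ± 0.035, and SLC6A9, a glycine transporter gene, by 0.52 ± 0.078. Cholesterol genes gave 18 rises and 6 genes not called of 24, and 22 rises adjusted over the list alone (median 0.362, camera adjusted p = 1.54e-71). NF-kB and secreted inflammatory genes gave 4 rises of 23, the same number adjusted over the list alone with 1 fall (median 0.0555, adjusted p = 6.69e-05, and 0.0643 with an estimated correlation). IL24, MMP1 and IL11 rose by 0.66 ± 0.067, 0.47 ± 0.064 and 0.30 ± 0.056. The IL11 call was lost without DMSO replicate 2 or 3, GSK343 replicate 2, any XL413 library or GSK343+XL413 replicate 3 (adjusted p up to 0.17).

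Cell cycle lists were lower with GSK343 in the presence of XL413 as well. MCM and licensing genes had 0 calls of 20 over all genes and 9 falls adjusted over the list alone (median −0.0994, adjusted p = 1.04e-05). G1/S genes had 1 fall of 28, CHAF1A, and 3 adjusted over the list alone (median −0.0785, adjusted p = 0.000515), and mitotic genes 2 of 32, PLK1 and CENPE, and 5 adjusted over the list alone (median −0.0881, adjusted p = 5.37e-06). CHAF1A was kept only without GSK343 replicate 3 or GSK343+XL413 replicate 2, PLK1 only without GSK343 replicate 2 or 3 or GSK343+XL413 replicate 2, and CENPE only without GSK343 replicate 3 or GSK343+XL413 replicate 1 or 2 (adjusted p up to 0.166, 0.168 and 0.176). Repair genes had 0 calls of 24 and 1 fall adjusted over the list alone (median −0.12, adjusted p = 6.69e-05, and 0.1 with an estimated correlation). Heat shock genes gave 2 falls of 15 and 6 adjusted over the list alone (median −0.0652, adjusted p = 5.37e-06), HSPA1A and HSPA1B, the latter at −0.39 ± 0.061 (lost without XL413 replicate 1, adjusted p = 0.0527). ATF4 targets gave 1 fall of 20, PSAT1, and 1 rise and 7 falls adjusted over the list alone (median −0.0837, adjusted p = 0.000515, and 0.139 with an estimated correlation).

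In the lysosome list SQSTM1 alone of 26 genes rose, by 0.53 ± 0.049, with 4 rises adjusted over the list alone (median 0.0279, adjusted p = 0.00106, and 0.167 with an estimated correlation). Interferon-stimulated genes (median 0.203, adjusted p = 0.00107), antigen presentation (0.0956, 0.00154) and NRF2 targets (0.0612, 0.00446) had 0 calls of 33, 20 and 17 over all genes and 0, 3 and 6 rises adjusted over the list alone. Their adjusted p were 0.513, 0.236 and 0.134 with an estimated correlation. The interferon call was lost without XL413 replicate 1 or GSK343+XL413 replicate 3 (adjusted p up to 0.0825). In all, edgeR called 121 genes, 86 higher and 35 lower, with 2317 at an unadjusted p under 0.05, against 104 higher and 24 lower with upper quartile scaling, 85 and 55 with RLE, and 126 and 168 with DESeq2. The GC and length correction gave 184 higher and 241 lower, and the fit without GSK343+XL413 replicate 2 129 and 123. FGFBP1 rose by 0.85 ± 0.142 and WNK4 fell by 0.37 ± 0.069, both lost without any XL413 library (adjusted p up to 0.104 and 0.152). CEP290 and KIF20B fell by 0.42 ± 0.080 and 0.39 ± 0.083, the first lost without DMSO replicate 1 or any XL413 library and the second kept only without GSK343 replicate 3 or any GSK343+XL413 library (up to 0.121 and 0.176). At least 2-fold, 1 gene was called, GCNT3 (2.67-fold, at a mean of −0.99 log2 CPM), chosen after its value was seen. The 121 calls became 76 and 76 without DMSO replicates 2 and 3, 40, 48 and 58 without XL413 replicates 1, 2 and 3, and 252 without GSK343+XL413 replicate 2. A fit of the 6 libraries alone called 18 genes and the GC and length correction 425.

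GSK343+XL413 against GSK343 asked what XL413 changed when GSK343 was present. HMMR rose by 0.54 ± 0.045 (adjusted p = 0.000345), from 73.9 ± 3.72 to 107 ± 3.75 CPM, CDK1 by 0.47 ± 0.046, UBE2C by 0.57 ± 0.064 and AURKA by 0.26 ± 0.030. HIST1H2AC, HIST1H2BK and CCL2 rose by 0.85 ± 0.094, 0.73 ± 0.094 and 0.63 ± 0.085, and MMP1 by 0.50 ± 0.064. CA9 fell by 1.33 ± 0.191, from 3.27 ± 0.250 to 1.30 ± 0.210 CPM, CENPE by 0.82 ± 0.112 and BCYRN1, a noncoding RNA of neurons, by 0.74 ± 0.097. Of 32 mitotic genes 13 rose, 1 fell, CENPE, and 18 were not called, and 18 rose and 5 fell adjusted over the list alone (median 0.155, camera adjusted p = 3.05e-09).

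MCM and licensing genes gave 2 rises of 20, MCM3 and MCM7 at 0.25 ± 0.038 and 0.15 ± 0.030, and 6 adjusted over the list alone (median 0.0707, adjusted p = 0.00143). MCM3 was lost without GSK343 replicate 3 or GSK343+XL413 replicate 1 and MCM7 in all fits but that without GSK343+XL413 replicate 2 (adjusted p up to 0.0631 and 0.218). Histones gave 3 rises of 13 and 4 adjusted over the list alone (median 0.218, adjusted p = 5.42e-06), with HIST1H2BD kept only without DMSO replicate 3 (up to 0.206). Of 28 G1/S genes RFC3 rose, a call kept only without GSK343+XL413 replicate 2 or 3 (up to 0.165), and 8 rose and 1 fell adjusted over the list alone. The adjusted p of that list was 0.0169, and 0.0618 with an estimated correlation (median 0.0504). NF-kB and secreted inflammatory genes gave 4 rises of 23, and 10 rises and 1 fall adjusted over the list alone. Their adjusted p was 3.87e-05, and 0.0618 with an estimated correlation (median 0.111). CXCL1 and CXCL8, of the latter list, rose by 0.31 ± 0.048 and 0.26 ± 0.053, CXCL1 lost without GSK343 replicate 2 or 3 (up to 0.0648) and CXCL8 kept only without GSK343+XL413 replicate 2 or 3 (up to 0.161). The lysosome list (GLA rose, 3 adjusted over the list alone, median 0.0597) had an adjusted p of 0.0052 and of 0.269 with an estimated correlation. The hypoxia list (CA9 fell, 4 adjusted over the list alone, median −0.0586) had 0.0198 and 0.102, and fibroblast markers (0 called by either adjustment, median 0.21) 0.0305 and 0.45. GLA was kept only without GSK343 replicate 1 or GSK343+XL413 replicate 2 or 3 (up to 0.218). List calls were lost for G1/S genes without GSK343 replicate 1 or 2 or GSK343+XL413 replicate 1 or 3 (up to 0.084), for hypoxia without GSK343 replicate 1 or GSK343+XL413 replicate 1 or 3 (0.118). The call for fibroblast markers was lost without GSK343 replicate 2 or GSK343+XL413 replicate 1 or 3 (0.213).

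In this comparison edgeR called 152 genes, 100 higher and 52 lower, with 3152 at an unadjusted p under 0.05. At least 2-fold, CA9 was the 1 gene called. Higher genes had a median transcript length of 2248 nt and lower genes of 4732 nt, and AKAP9, a long centrosomal scaffold gene, fell by 0.88 ± 0.136 (lost without GSK343 replicate 3, adjusted p = 0.0544). UBE2S, ATOH8 and GAGE12D, the last a member of a family of near-identical paralogs, rose by 0.71 ± 0.121, 0.64 ± 0.108 and 0.63 ± 0.138. PDE3A and FAM196B fell by 0.69 ± 0.121 and 0.78 ± 0.170, and all 5 calls were lost without GSK343 replicate 3 (adjusted p 0.103, 0.103, 0.218, 0.103 and 0.155). UBE2S was also lost without GSK343 replicate 2 or GSK343+XL413 replicate 1, ATOH8 without GSK343 replicate 2 and PDE3A without GSK343+XL413 replicate 1, and GAGE12D was kept only without DMSO replicate 1 and FAM196B only without GSK343+XL413 replicate 1. The 152 calls became 73, 61 and 70 without DMSO replicates 1, 2 and 3, 38 and 35 without GSK343 replicates 2 and 3, 63, 66 and 71 without XL413 replicates 1, 2 and 3, and 62, 243 and 348 without GSK343+XL413 replicates 1, 2 and 3 (the last with 174 higher and 174 lower). DESeq2 called 582 genes (316 higher and 266 lower), the GC and length correction 645 (341 and 304), and an edgeR fit of the 6 libraries alone 0, with 1831 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0782.

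The interaction asked whether the combination differed from the sum of both single log2 changes. EdgeR called 0 genes (smallest adjusted p 0.766), with 413 genes, 2.67%, at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 2. The genes called by DESeq2, chosen after their values were seen, were CA9 (−1.65 ± 0.326, adjusted p = 0.00351; edgeR gave −1.63 ± 0.277 with an adjusted p of 0.766) and BAGE5, which had a count in 3 of the 12 libraries. The GC and length correction called 1 gene, GOLGA4 (−0.36 ± 0.049, adjusted p = 0.0474). The median SE of the interaction was 0.0891 among 10099 genes above 3 log2 CPM, against 0.063 for XL413 against DMSO. Of the gene lists, 7 passed camera's test, each with 0 members called over all genes: cholesterol synthesis, G1/S genes, ATF4 targets and heat shock were above the sum, and interferon-stimulated genes, NF-kB and secreted inflammatory factors, and hypoxia below it. With an estimated correlation 1 of them held, cholesterol synthesis (median 0.102, adjusted p = 0.000231, and 0.0308 with an estimated correlation), in which 20 of 24 estimates were above 0, and it was also the 1 list kept without any 1 library. G1/S genes were kept only without GSK343 replicate 3 or GSK343+XL413 replicate 2 (adjusted p up to 0.147), heat shock only without XL413 replicate 3 (0.208). ATF4 targets were lost without DMSO replicate 1, GSK343 replicate 3, XL413 replicate 1 or 2 or GSK343+XL413 replicate 2 (0.114). Interferon-stimulated genes were lost without DMSO replicate 2 or 3, GSK343 replicate 2 or 3, XL413 replicate 3 or GSK343+XL413 replicate 1 (0.889), NF-kB genes without GSK343+XL413 replicate 1 (0.0642) and hypoxia genes without replicate 3 (0.0664). The compound targets and partners had 0 called members in the interaction (adjusted p = 0.909).

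Effects of each compound without and with the other were compared across genes, with no library in common. They do share 1 estimate of the spread for each gene, so the overlap of independent lists may understate what chance would give. GSK343 gave 180 called genes against DMSO and 121 against XL413, and 78 were called in both in the same direction and 0 in opposite directions, where 0.78 would be shared by independent lists. Of the 180, 177 had the same sign in the presence of XL413, with a median ratio of 0.798, and across all tested genes r was 0.204 (rho 0.427). For XL413, 44 genes were shared of 66 and 152 (0.36 for independent lists, 0 opposite), 65 of 66 had the same sign, the median ratio was 0.887, and r was 0.215 (rho 0.476). Taken the other way, from the 121 and 152 genes called in the presence of the other compound, the median ratios were 0.855 and 0.747. Choosing genes by their calls in 1 comparison lowers such ratios, so they do not show a weaker effect in the presence of the other compound. HMGCS1, INSIG1, MMP3 and PTGES were among the first set of shared genes, and HMMR, CDK1, HIST1H2AC and CCL2 among the second. The 2 values of r ranged from 0.172 to 0.359 and from 0.093 to 0.301 over the fits that left out 1 library, and they were 0.571 and 0.65 with the stricter filter and 0.035 and 0.045 with no filter.

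XL413 and GSK343 against DMSO share the DMSO libraries, which by itself makes their estimates alike. They had 7 calls in the same direction and 3 in opposite directions, against 0.41 in the same direction for independent lists. Across all tested genes r was 0.436 and rho 0.293, below the means of 0.514 and 0.454 in 20 simulations of unchanged groups against shared controls, while the covariance of 0.0301 lay above their mean of 0.0245 (SD 0.0024). The simulations used the spread of all 12 libraries, including GSK343+XL413 replicate 2, which is in neither comparison. With that library the median SE of XL413 against DMSO was 0.063, and without it 0.0481, so the simulated covariance may be too high. These values leave open whether the effects of the 2 compounds are alike across genes. TUBA1A, ACSS2, CXCL8, MMP1, TGFBI and TRIM34 rose and HSPA1A fell with either compound, while AURKA rose with XL413 and fell with GSK343, and FST and UCA1 fell with XL413 and rose with GSK343, all chosen here after their values were seen. The 7 shared calls became 149 without GSK343+XL413 replicate 2 and 0 to 4 without any other library, and the 3 opposite calls became 27 without that replicate, 0 without any DMSO or XL413 library, 1 without any GSK343 library or GSK343+XL413 replicate 1, and 2 without its replicate 3. Of the 10 genes, 0 were called with both compounds in all 12 fits that left out 1 library. With XL413 the MMP1 call was lost without any DMSO or XL413 library (adjusted p up to 0.152), and those of ACSS2 and TGFBI without replicate 2 or 3 of either group (0.0796). HSPA1A was kept only without XL413 replicate 3 or GSK343+XL413 replicate 2 (0.257), TRIM34 only without these or GSK343+XL413 replicate 1 (0.21), and TUBA1A only without GSK343 replicate 1 or 3 or any GSK343+XL413 library (0.192). With GSK343 ACSS2 was kept only without GSK343+XL413 replicate 2 (0.194), CXCL8 only without its replicate 2 or 3 (0.172) and TUBA1A only without these or GSK343 replicate 3 (0.17). MMP1 was lost without any DMSO library or GSK343 replicate 2 or 3 (0.131) and TGFBI without any DMSO or GSK343 library (0.104). With GSK343 the AURKA call (−0.14 ± 0.030) was kept only without GSK343+XL413 replicate 2 and the FST call (0.20 ± 0.042) only without replicate 2 or 3 of that group (adjusted p up to 0.193 and 0.162). With XL413 the AURKA call was lost without DMSO replicate 2 (0.0549) and the UCA1 call (−0.26 ± 0.042) without any DMSO or XL413 library (0.138).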

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

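The tests on splits and the removal of trends and of depth in this part were chosen before their results were seen; the test of the share of small interaction p, the averaged effects and the comparison of splits with the compounds' effects were chosen after. By a camera test of the interaction at its preset correlation, 7 gene lists passed, of which 1, cholesterol synthesis, passed at an estimated correlation; 0 genes were called on their own by edgeR (413 at an unadjusted p under 0.05, 0 called by limma-voom, 2 by DESeq2). Cholesterol genes lay above the sum of both single changes by a median log2 value of 0.102 (adjusted p = 0.000231), ATF4 targets by 0.0693 (0.011), G1/S genes by 0.0565 (0.0237) and heat shock genes by 0.047 (0.0352). Interferon-stimulated genes lay below it at −0.107 (0.0137), hypoxia and glycolysis genes at −0.082 (0.00385) and NF-kB and secreted inflammatory genes at −0.0711 (0.00385). At an estimated correlation the adjusted p were 0.0308 for cholesterol genes, 0.389, 0.123 and 0.161 for ATF4 targets, G1/S genes and heat shock, and 0.653, 0.103 and 0.192 for the 3 lists below the sum. Cholesterol synthesis was the 1 list of the 7 kept in all 12 fits that left out 1 library (adjusted p up to 0.00596).

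For the interaction the real split called 0 genes, which all 100 splits of the 12 libraries reach by construction, so that this count says nothing about chance. The highest other split called 1037 genes, 10 other splits at least 1 and 4 more than 100. By a comparison chosen after these counts were seen, the contrast of these 4 splits equals the averaged effect of a compound, XL413 in 3 and GSK343 in 1. The structure they point to is thus that of the groups, and the other 95 splits called at most 1 gene.

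The first pattern weighed is that GSK343+XL413 replicate 2 stood apart. After trends with GC content and transcript length were removed, the SD of its deviation was 0.223, against at most 0.157 in the other 11 libraries, and after all libraries were thinned to the smallest total it was 0.277, against at most 0.178. Both values argue against depth, and against the trends as fitted here, as the whole cause, although the length trend of this library (rho −0.641) was the strongest of the 12. The trends used the longest annotated transcript of each gene, so a length effect through other transcripts was not tested. A difference in the preparation of that library, or in the cells of that sample, may lie behind it and was not tested, since the labels used here give no batch.

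The second pattern is that more genes were called with the combination than with the single compounds. With all libraries the calls for the combination were 8.75 times the sum of those for both single compounds, and without GSK343+XL413 replicate 2 the ratio was 1.36 (2335 genes, against 756 and 958). The ratio fell because calls for the single compounds rose, from 66 and 180. Those for the combination did not fall, from 2152. In fits of only the groups compared the pattern was not kept, with 1333 genes for XL413, 408 for GSK343 and 671 for the combination. The fits of the single compounds leave out that library, and the fit of the combination holds it. That library may therefore account for most of the contrast in calls, but a ratio between 1 and 1.5 leaves open whether it accounts for all of it. Whether departures from the sum of both single changes add to it cannot be told apart either: interaction p under 0.05 made up 2.67% of genes, and 2.81% without that library, shares under the 5% that a calibrated test would give, so that this test was conservative and excludes nothing. Without GSK343+XL413 replicate 3 the share was 5.5%.

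The third pattern is that 6 mitotic genes were lower with the combination, ASPM, CENPE, CENPF, KIF11 and MKI67, with transcripts of 4860 to 12678 nt, and PLK1, with one of 2227 nt, near the median of 2150 nt of the 10 higher mitotic genes. Without GSK343+XL413 replicate 2 their median log2 change was −0.342, against −0.537 with it, and with GC and length trends removed −0.454, with all 6 called in both. Of the 10 higher mitotic genes, all were called without that library and 7 with the trends removed. The correction lowered the log2 values of the other 3, chosen after they were seen, by more than their SE shrank: AURKA from 0.11 ± 0.030 to 0.04 ± 0.026, CCNB1 from 0.16 ± 0.037 to 0.067 ± 0.025 and NEK2 from 0.16 ± 0.048 to 0.051 ± 0.043. The trend of that library does not account for the whole of the change in the 6 lower genes, though the distance between the medians may be due to it. With XL413 alone, in libraries other than that one, MKI67 was at 425.2, 395.4 and 401.5 CPM, against 530.5, 556 and 555.3 with DMSO. CENPE was at 56.84, 52.42 and 53.4 CPM, against 61.78, 66.03 and 64.44 with DMSO. Neither gene was called with XL413, and the XL413 and DMSO levels of KIF11 and PLK1 overlapped. With GSK343 alone KIF11 was at 180.9, 175.9 and 193.5 CPM, against 195.6, 207.7 and 203.6 with DMSO. PLK1 was at 223.4, 232 and 230.9 CPM with GSK343, against 262.8, 260.5 and 258.2 with DMSO. Of these genes PLK1 was called with GSK343, a call kept in 6 of 12 fits that left out 1 library. The GSK343 and DMSO levels of MKI67 and CENPE overlapped. Lower levels of MKI67, CENPE, KIF11 and PLK1 were thus not confined to the combination or to that library. No biological explanation was tested.

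With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. In each of the 5 comparisons the real split was the 1 with as many calls, with 66 genes for XL413 (highest other split 1), and 180, 2152, 121 and 152 for GSK343, the combination, and the combination against XL413 and against GSK343 (highest other split 0 in these 4). Effects averaged over both backgrounds, added after the data were seen, allow more splits. For XL413 the real 1408 genes were reached by 1 of 100 splits, the real one (highest other 33), and for GSK343 the real 1012 by 1 of 100 (highest other 0). This makes a chance split unlikely for both but does not exclude it, since 1 of 100 is the smallest share possible here. Splits that mix the groups also widen the spread, which lowers their calls.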

How the results depend on the processing

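The correction for GC content and length and the averaged effects were chosen after seeing the data, and the other alternatives before. No named gene or list past its test changed direction. The side with more calls did change. It went from higher to lower for XL413 and GSK343 with the GC and length correction and without GSK343+XL413 replicate 2, for XL413 in the fit of its groups alone, for the combination against XL413 with that correction and with DESeq2, and for the combination against GSK343 without GSK343 replicate 3 and at least 2-fold. It went from lower to higher for the combination against DMSO with upper quartile factors, with the stricter filter and at least 2-fold. The averaged effects, with near equal sides, changed in 9 fits. Of the named genes' results, 320 stayed on the same side of the threshold with RLE factors, 308 with upper quartile factors, 320 with limma-voom, 274 with DESeq2 and 269 with the GC and length correction. With DESeq2 38 more of them gained a call and 0 lost it, and with the GC and length correction 50 gained and 4 lost it. Of the 61 list results, 60 did with RLE, 58 with upper quartile factors, 61 with the replicate block and 25 with an estimated correlation in camera, where 36 lost their call. For genes called with XL413, GSK343, the combination, the combination against XL413 and the combination against GSK343, values outside 1.5 times those reported were as follows. The GC and length correction gave 576, 651, 425 and 645 (for all but the combination against DMSO), and 1 gene for the interaction. Fits of the groups compared alone gave 1333, 408, 671, 18 and 0 (1831 genes at an unadjusted p under 0.05 for the last), which have fewer libraries for the spread and leave out GSK343+XL413 replicate 2 in the first 2. DESeq2 gave 245, 338, 294 and 582 (all but the combination against DMSO) and 2 for the interaction. At least 2-fold, 1, 4, 48, 1 and 1 genes were called, by the limit itself. Same-numbered libraries did not as a rule deviate together (median r −0.051, from −0.415 to 0.34, and a median of 0.046 for other pairs). This leaves open whether the replicate numbers mark shared days or cultures. A block for them gave 108 genes for GSK343 and an overlap of calls of 2 between XL413 and GSK343, and the GC and length correction gave an overlap of 91. Lists past the test with an estimated correlation numbered 3, 8, 5, 5, 3 and, for the interaction, 1; with fry 16 for the combination and 4 for the interaction; with the stricter filter 5 for the combination against GSK343 and 4 for the interaction. The correlation of GSK343 effects without and with XL413 was 0.035 with no filter and 0.571 with the stricter filter, and that of XL413 effects 0.045, 0.65 and, with the GC and length correction, 0.316. The filters differ in the number of low genes; for the other alternatives the cause was not tested. Without each library in turn, the counts ran from 16 to 756 (XL413), 37 to 958 (GSK343), 850 to 2610 (combination), 40 to 252 (against XL413), 35 to 348 (against GSK343) and 0 to 0 (interaction), the averaged effects from 523 to 2145 (XL413) and 448 to 2009 (GSK343), and the lists called from 6 to 10, 12 to 17, 7 to 10, 11 to 13, 5 to 9 and 3 to 5 in the same order. The correlations ran from 0.172 to 0.359 and from 0.093 to 0.301, and the overlap from 0 to 149. The highest counts for both single compounds came without GSK343+XL413 replicate 2, which widens the shared spread. Depth limits the genes near the count minimum of 10.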

Other observations

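The averaged effects and the genes named in this part were chosen after the data were seen. Averaged over both backgrounds, lists of the cell cycle were lower with GSK343, with most members not called. With edgeR, 8 of 20 MCM and licensing genes fell (camera adjusted p = 1.17e-08), 9 of 28 G1/S genes fell (4.4e-08) and 8 of 32 mitotic genes fell (7.35e-08), with 0 rises in each (medians −0.115, −0.101 and −0.0895), while 19 of 24 cholesterol genes rose (median 0.353, 4.55e-73) and 10 of 15 heat shock genes fell (2.17e-11). With XL413 16 of 32 mitotic genes rose and 4 fell (3.06e-13), 4 of 20 MCM and licensing genes rose (0.000727), and 9 of 28 G1/S genes rose and 3 fell in a list that did not pass (0.095). Histones gave 4 rises of 13 (2.01e-09), and 10 NF-kB and secreted inflammatory genes rose and 1 fell (1.53e-11).

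Among weakly expressed genes, TRIM34, a tripartite motif gene, was at 0.92 ± 0.117 CPM with DMSO and at 1.97 ± 0.473, 2.48 ± 0.256 and 1.99 ± 0.312 CPM with XL413, GSK343 and both. It rose at least 2-fold with either compound (log2 1.09 ± 0.210 and 1.43 ± 0.204) and by 1.10 ± 0.209 with both. The XL413 call of TRIM34 was lost in 9 of 12 fits that left out 1 library (adjusted p up to 0.21), and its GSK343 call was kept in all 12. The keratin gene KRT75 and GCNT3, a gene of mucin glycosylation, were higher where GSK343 was present: KRT75 rose by 1.60 ± 0.227 and GCNT3 by 1.28 ± 0.216 averaged over both backgrounds, at fewer than 1 CPM.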
